A study of Mus musculus with 20 samples.

How the data were processed

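Single-cell gene expression and guide libraries were measured from the neocortex of 2-week-old Cas9 mice, sorted for the red fluorescent protein of the vector. The libraries were made with the 10x Genomics 3' workflow, and guide sequences were enriched from the same cDNA. The authors made a matrix of raw UMI counts per feature and barcode for each library with Cell Ranger 6.1.2, per the file headers, on mm10, per the labels. The settings of barcode calling are not given in the sources used here. Of the genes in the matrices, 32158 matched the GENCODE vM21 annotation by identifier, and 85 features counted guides. The guide samples have no matrices apart from these, so guide counts came from the guide features. No other values were used.

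Depth differed between libraries. Barcodes ranged from 2608 to 40385 and total UMIs from 22486609 to 172028863 per library, and the report gives each total. Floors for genes at 0 counts use 3 counts of the UMIs summed over the group, and cover counting error only. Groups came from the labels: 4 libraries have names ending in F and 6 in M. The labels do not spell the letter out.

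Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were retained (95943 of 113874). Doublets were marked per library with Scrublet as run in scanpy 1.11.5. In 5 libraries the automatic threshold marked under 0.5%, and there the top 2.65% of scores were marked, the mean share of the other libraries; this fallback was set after the scores had been seen. The 93336 remaining cells were clustered in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9) with Leiden at resolution 1.0 on 15 neighbours in 30 principal components of 2000 variable genes, seed 1. Genes of the fixed lists and X-inactivation, Y-linked, mitochondrial, ribosomal and hemoglobin genes were left out of the variable genes. Each cluster took the class with the most markers past a log2 fold of 1 in at least 20% of its cells, out of 18 marker lists, with at least 4 markers needed. The count of markers replaced a mean fold, and the minimum of 4 was set, after the clusters had been seen.

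Counts were summed per library and class where at least 20 cells were present. For the comparison by class, classes with at least 6 such libraries were kept: 12 classes, 115 sums, 15512 genes and 94 residual degrees of freedom. edgeR 4.0.16 in R 4.3.3 fitted quasi-likelihood models (glmQLFit, glmQLFTest) with TMM factors and filterByExpr, the library as a block, and the contrast of each class with the mean of the others. CPM are counts scaled to 1e6 on TMM-adjusted totals of the same fit. The same model gave contrasts between pairs of classes, chosen after the values by class had been seen. F and M libraries were compared within each class with at least 3 libraries of each, without covariates. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

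For guides, a cell had a target called when a guide's UMIs had a binomial p under 1e-4 against the guide's background share and at least 3 UMIs. Cells with 1 target were compared. The planned test, at least 20 cells with the guide and 20 with the GFP guide per library and class, could not be run in any class. In its place, after the cell counts had been seen, guide cells were set against the GFP guide with at least 5 cells per arm in at least 3 libraries, against the GFP guide over all classes, against other targets in the class, and against 5 cells with other targets per guide cell, matched on library and class or on library and cluster. These used edgeR with the library as a block. Class shares were compared by exact two-sided permutation tests. DESeq2 1.42.0 served as a second tool, and limma 3.58.1 gave the camera tests with a preset correlation of 0.01 and with an estimated one; matplotlib 3.10.9 drew the figures and version 1.17.8 of data.table read the tables.

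The comparisons, lists and alternatives were fixed before the data were examined, apart from those named here as chosen later. The 17 fixed lists were the targets, Y-linked genes, X-inactivation and escape, H2A.Z and its exchange, H4K20 methylation, autism genes, schizophrenia exome genes, immediate early, heat shock, microglial activation, interferon response, p53 targets, cell cycle, cholesterol synthesis, myelin, synaptic and oxidative phosphorylation; camera tested 15 of them. Genes were named by a fixed rule. By class these were both targets, the most raised and the most reduced called member per class of the H2A.Z, H4K20, autism and schizophrenia lists, and the 2 called members with the largest absolute log2 difference of each other list. For F against M they were the called genes, at most 15 per class, and the X-inactivation and Y-linked lists. For guides they were the targets and at most 15 called genes per class and target. Genes were left out for length.

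Alternatives were: at least 1000 genes per cell, at most 5% mitochondrial UMIs, doublets kept, at least 50 cells per sum, no filter on low counts, RLE size factors, DESeq2, no replicate block, counts thinned to the same median UMIs per cell, Leiden resolution 0.5, the rerun suffix as a covariate or as a filter, each library left out, and, added after the data had been seen, the removal of barcodes shared between libraries, these settings applied to guide UMIs by class, the list tests by class with an estimated correlation and no replicate block, and guide calls of at least 5 UMIs or a binomial p under 1e-6. F against M was also fitted for up to 100 splits of the libraries, and the guide arms were exchanged within libraries in up to 60 ways.

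The models were tested on simulated data, in which 200 genes of the real sums were scaled. The model by class recovered 93% of 2-fold and 92% of 4-fold changes with 2.63% false calls. In that simulation every class had the same means before the 200 genes were scaled. In the real data edgeR called at least 3464 genes higher in each class, so the 2.63% does not cover those contrasts. F against M recovered between 4% (endothelial-like) and 79% (OPC-like) of 2-fold changes, and between 61% and 100% of 4-fold changes. Its false calls ran from 1.82% (neuroblast or progenitor-like) to 7.10% (astrocyte-like). For guides against matched cells, 77% and 97% were recovered for Anp32e and 81% and 93% for Kmt5a, with 6.45% and 6.95% false calls. Against the GFP guide in ependymal-like cells 11% and 74% were recovered for Anp32e. The simulated counts were drawn separately for each gene, so these shares do not cover changes that many genes share within a library. Results for some genes of the lists and for 1 further target are not reported here.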

Results

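Single cells from the neocortex of 2-week-old mice were profiled after infection at birth with a pooled lentiviral library of guide RNAs. The mice carried a Cas9 transgene, the enzyme that cuts DNA where a guide directs it, and cells were sorted for the red fluorescent protein encoded by the virus. The labels name Anp32e and Kmt5a as the genes under study, the first mapped to a locus shared by several psychiatric disorders and the second to a locus tied to a single disorder. Expression counts came from 10 libraries, 4 with names ending in F (replicates 1, 2, 5 and 9) and 6 with names ending in M (replicates 3, 4, 6, 7, 8 and 10). The matrices held counts of genes and of 85 guide features against 43 targets. The libraries held 113874 barcodes, and 93336 cells remained after filtering and removal of doublets. The F libraries had totals of 73807739, 67617875, 133276479 and 38093746 UMIs in replicates 1, 2, 5 and 9. The M libraries had totals of 42925926, 22486609, 172028863, 159059033, 147181367 and 59035033 UMIs in replicates 3, 4, 6, 7, 8 and 10. The median of retained cells ranged from 1829 UMIs in M replicate 7 to 14312.5 UMIs in M replicate 3.

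Anp32e (ENSMUSG00000015749) lies on chromosome 3 of mm10, from 95929246 to 95947390 on the + strand, and encodes a chaperone that removes the histone variant H2A.Z from chromatin. Kmt5a (ENSMUSG00000049327) lies on chromosome 5, from 124439930 to 124462308 on the + strand, and encodes the methyltransferase that places a single methyl group on lysine 20 of histone H4. Both are annotated as protein coding. The guides against Kmt5a carry its older name, Setd8.

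The sorted cells fell into 13 classes named by fixed marker lists, and each class is written below with the ending "-like" because the names rest on markers alone. Astrocyte-like cells made up 20.9% ± 8.46 of each library (mean ± SD, 10 libraries), ependymal-like cells 19.5% ± 11.2, excitatory neuron-like cells 12.6% ± 6.71 and inhibitory neuron-like cells 8.30% ± 5.60. Microglia-like cells made up 6.75% ± 5.36, neuroblast or progenitor-like cells 5.63% ± 2.93, fibroblast-like cells 3.88% ± 3.68 and oligodendrocyte precursor (OPC)-like cells 3.67% ± 1.69. Border macrophage-like, endothelial-like, committed oligodendrocyte-like, mature oligodendrocyte-like and mural-like cells made up 1.497%, 1.39%, 1.15%, 0.986% and 0.188%. No cluster took the name of choroid plexus epithelial, erythroid, T or NK, B, or neutrophil or monocyte cells. Cells in clusters without a name made up 27.4% of F replicate 1 and at most 8.64% of the other F libraries, and 36.2% of M replicate 7 and at most 16.1% of the other M libraries. M replicate 7 gave 83.0% of the largest such cluster of 10902 cells, whose median was 1102 UMIs. No class share passed between F and M libraries in an exact two-sided permutation test over 210 splits (smallest possible p = 0.00476). The smallest unadjusted p was 0.181, for microglia-like cells, whose mean share was 3.81% in F and 8.71% in M libraries (adjusted p = 0.990, exact permutation test).

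The next comparison asks which of the sorted classes express the 2 genes under study. Anp32e was highest in neuroblast or progenitor-like cells, at 502 ± 76.9 counts scaled to library size (CPM; mean ± SD, 10 libraries), a log2 difference of 2.11 (SE 0.07) from the mean of the other classes. Of the 4660 cells of that class, 4017 were in 1 cluster with Cenpf, Ccna2 and Top2a, genes of cell division, among its top genes. The class name thus does not single out neuroblasts. Anp32e was also high in OPC-like cells (231 ± 35.9 CPM, log2 0.88) and committed oligodendrocyte-like cells (204 ± 37.1 CPM, log2 0.69, 8 libraries), and low in inhibitory neuron-like cells (77.1 ± 14.3 CPM, log2 -0.85). Kmt5a was highest in mature oligodendrocyte-like cells, at 265 ± 57.3 CPM (8 libraries) and a log2 difference of 2.07 (SE 0.08). It followed in neuroblast or progenitor-like cells (137 ± 19.8 CPM, log2 1.10) and committed oligodendrocyte-like cells (114 ± 25.9 CPM, log2 0.85), and was low in astrocyte-like cells (34.0 ± 5.80 CPM, log2 -1.09) and inhibitory neuron-like cells (32.2 ± 5.44 CPM, log2 -1.16). Each gene, in the 3 classes where it was highest, exceeded the mean of the other classes in every library tested.

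Across the oligodendrocyte lineage the genes moved in opposite directions. Mature oligodendrocyte-like cells had less Anp32e than OPC-like cells (log2 -1.45, SE 0.14, higher in 0 of 8 libraries) and more Kmt5a (log2 1.85, SE 0.12, higher in 8 of 8). From OPC-like to committed oligodendrocyte-like cells Kmt5a rose by a log2 of 0.73, while the change in Anp32e (log2 -0.18) had an adjusted p of 0.311. From committed to mature cells, in 7 libraries, Anp32e fell by 1.27 on the log2 scale and Kmt5a rose by 1.12. Neuroblast or progenitor-like cells exceeded excitatory neuron-like cells by a log2 of 2.40 for Anp32e and 1.80 for Kmt5a, and inhibitory neuron-like cells by 2.71 and 2.07, in 10 of 10 libraries each. Excitatory neuron-like cells exceeded inhibitory neuron-like cells by 0.31 for Anp32e (adjusted p = 0.0235, 8 of 10 libraries) and 0.27 for Kmt5a (adjusted p = 0.0433, 9 of 10 libraries). These pairs of classes were chosen after the values by class had been seen.

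The edgeR test also covered the other classes. Anp32e was lower in excitatory neuron-like (log2 -0.51), endothelial-like (-0.59), ependymal-like (-0.69), fibroblast-like (-0.69) and mature oligodendrocyte-like cells (-0.70). Kmt5a was higher in microglia-like cells (84.9 ± 24.3 CPM, log2 0.36, above the other classes in 6 of 10 libraries) and lower in endothelial-like (-0.53), fibroblast-like (-0.58) and excitatory neuron-like cells (-0.87). Anp32e in microglia-like (0.09) and border macrophage-like cells (0.02), and Kmt5a in OPC-like (0.05) and border macrophage-like cells (-0.04), did not pass. Anp32e was called in astrocyte-like cells (log2 0.23, adjusted p = 0.00963, above the other classes in 3 of 10 libraries), but the call ended without M replicate 4 (0.14), M replicate 6 (0.08), F replicate 9 (0.05), M replicate 10 (0.05) or the replicate block (0.06). Kmt5a in ependymal-like cells (log2 -0.17, adjusted p = 0.0563, above the other classes in 1 of 10) was called without F replicate 2 (-0.19), 5 (-0.20) or 9 (-0.27), without M replicate 3 (-0.25), 6 (-0.22), 7 (-0.18) or 10 (-0.25), and without the replicate block (-0.24).

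**Figure D1:**
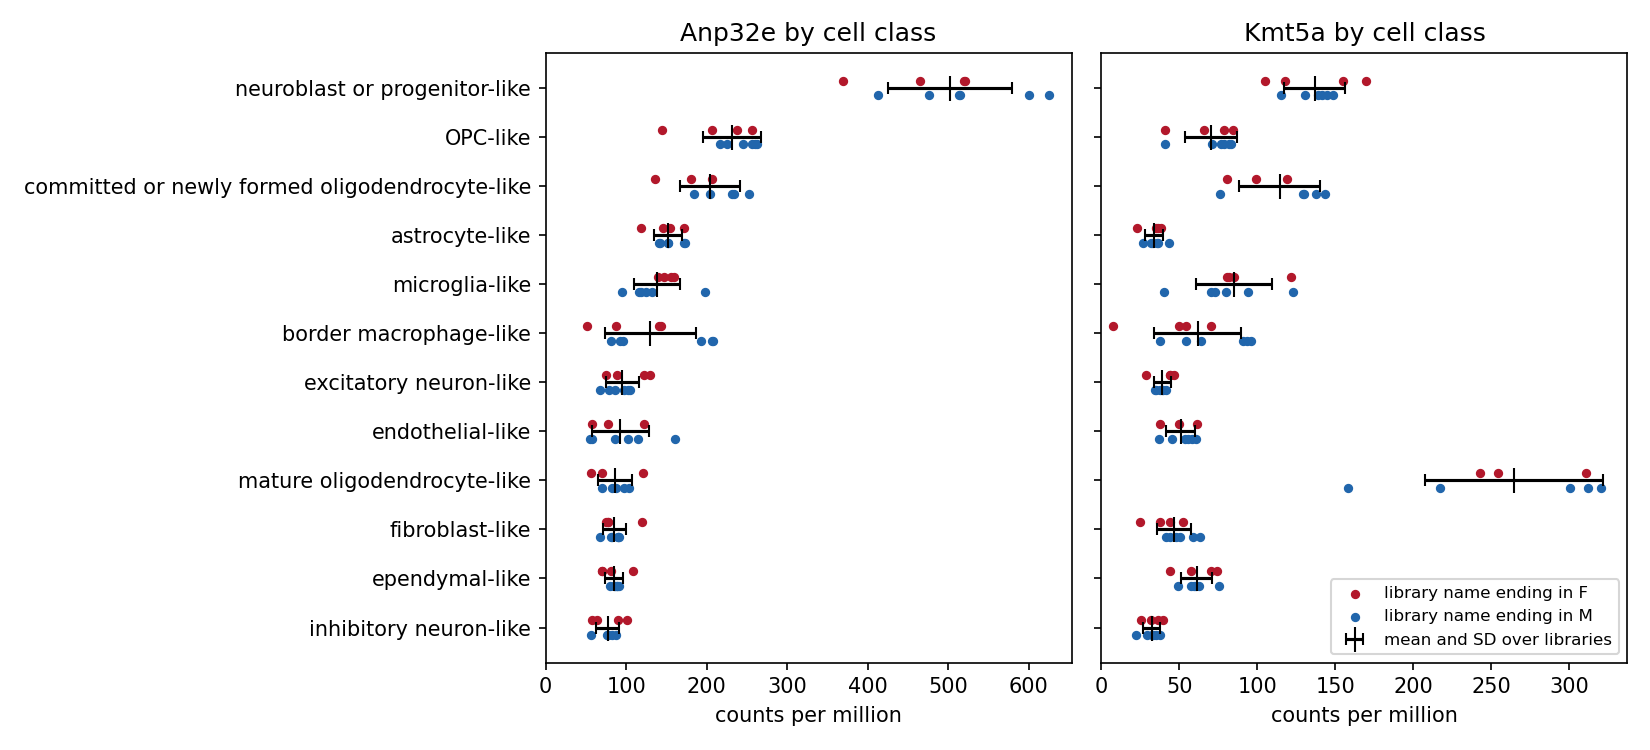
CPM of Anp32e and Kmt5a in each cell class, with 1 point per library (F red, M blue) and the mean and SD as bars. Anp32e is highest in neuroblast or progenitor-like cells at 502 CPM and Kmt5a in mature oligodendrocyte-like cells at 265 CPM.

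The lists of genes fixed in advance describe what else set the classes apart, and the account starts with neuroblast or progenitor-like cells, where Anp32e was highest. Of 21 genes of H2A.Z and its exchange, 19 were higher and 0 lower there, led by H2afv, which encodes the second H2A.Z protein, at 1314 ± 190 CPM (log2 2.91, SE 0.09, 10 of 10 libraries). Of 17 genes of H4K20 methylation 10 were higher, led by Dtl, part of the ligase that degrades Kmt5a protein, at 77.6 ± 11.3 CPM (log2 3.88, SE 0.14). All 22 cell cycle genes were higher, led by the mitotic kinase Aurkb (149 ± 28.9 CPM, log2 5.92) and the cyclin Ccna2 (log2 5.74); 3 of the cell cycle genes are markers that named the class. Of the autism genes, the transcription factor Tcf4 was highest (log2 1.31) and the sodium channel gene Scn2a lowest (log2 -1.81). The camera test called H2A.Z exchange (adjusted p = 0.00404 with an estimated correlation) and the cell cycle (adjusted p = 0.0137 with an estimated correlation) higher under both correlations, while H4K20 methylation (adjusted p = 0.122 with an estimated correlation) and 7 genes of X-inactivation and escape (adjusted p = 0.226 with an estimated correlation) were called with the preset value alone.

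Myelin genes were higher in the 2 later oligodendrocyte classes, and cholesterol synthesis genes in the mature one; 11 of the myelin genes are markers that named the mature class. In mature oligodendrocyte-like cells all 14 were higher, led by Mog and Mobp, which encode myelin proteins (log2 10.63 and 10.42, 8 of 8 libraries). All 20 genes of cholesterol synthesis were higher too, with the cyclase gene Lss at a log2 of 3.67. Of the 21 genes of H2A.Z exchange 14 were lower, with H2afz itself at a log2 of -1.48, and 2 were higher, with the histone chaperone gene Nap1l4 at 0.83; camera called the list lower with the preset correlation (adjusted p = 0.496 with an estimated correlation). Of the H4K20 list Kmt5a was the most raised and Dtl the most reduced (log2 -1.69). Of 25 autism genes 15 were lower and Asxl3 alone was higher (log2 2.72; adjusted p = 0.522 for the list with an estimated correlation). The p53 target Phlda3 was higher (log2 3.55).

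Committed oligodendrocyte-like cells had 9 myelin genes higher, with Ugt8a at a log2 of 5.75, and Trio was the most raised of the schizophrenia exome genes (log2 2.28). They had the H2A.Z list's Anp32b at 0.96. OPC-like cells had 13 of the 21 H2A.Z genes higher, led by Anp32e itself, with the remodeller subunit gene Znhit1 lower (log2 -0.41); camera called the list with the preset correlation (adjusted p = 0.538 with an estimated correlation). The glutamate receptor gene Gria3 was higher in OPC-like cells (log2 2.98). All 21 immediate early genes were lower in OPC-like cells, led by Junb (log2 -3.34) and Zfp36 (log2 -3.04), and 20 of them in committed oligodendrocyte-like cells, led by Atf3 (log2 -2.47). Camera called these with the preset correlation (adjusted p = 0.160 and 0.0800 with an estimated correlation). In OPC-like cells the p53 target Cdkn1a, an inhibitor of the cell cycle, was at a log2 of -3.58 and the heat shock gene Hspb1 at -2.48. Camera called myelin in both later classes also with the estimated correlation (adjusted p = 0.0110 in committed and 3.08e-07 in mature cells), and cholesterol synthesis in mature cells (adjusted p = 0.00307). The call for cholesterol synthesis in OPC-like cells, 15 of 20 genes higher, was not kept (adjusted p = 0.618 with an estimated correlation).

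Genes of the microglial activation list were higher in both microglia-like and border macrophage-like cells. All 19 genes of microglial activation were higher in microglia-like cells, led by the chemokine genes Ccl4, at 8116 ± 3684 CPM (log2 9.07, SE 0.27, 10 of 10 libraries), and Ccl3 (log2 8.78). In border macrophage-like cells 18 were higher, led by Ccl2 (5229 ± 2532 CPM, log2 9.08) and Cxcl2 (log2 8.78). Both calls held in camera with an estimated correlation (adjusted p = 0.00430 and 0.0129). The contrast was with the mean of all other classes, most of them not macrophage-like. These calls therefore do not tell activation from the identity of the classes. The p53 target list included Gdf15, a stress cytokine gene, at a log2 of 6.16 in microglia-like and 6.64 in border macrophage-like cells, and the cell death gene Pmaip1 at 4.70 in microglia-like cells. Immediate early genes were led by Atf3 (log2 3.39) and Egr2 (log2 3.24) in microglia-like and by Ier3 (log2 4.54) in border macrophage-like cells. Border macrophage-like cells also had 11 of 13 heat shock genes higher, with Hspa1b at 4.70 and Hspa1a at 4.46, 20 of 22 interferon response genes higher, with Ifi27l2a at 6.61, and all 22 cell cycle genes higher, with Mki67 at 3.87 and Cenpa at 3.71. All 20 genes of cholesterol synthesis were lower in both, with Fdps at -2.27 in border macrophage-like and Hmgcs1 at -1.74 in microglia-like cells, and 21 of 24 genes of oxidative phosphorylation were lower in border macrophage-like cells, with Ndufv1 at -1.09. In border macrophage-like cells the calls for heat shock, interferon response, cell cycle, cholesterol synthesis and oxidative phosphorylation had an adjusted p of 0.244, 0.193, 0.244, 0.291 and 0.370 with an estimated correlation, and cholesterol synthesis in microglia-like cells 0.866. The licensing factor Cdt1 of the H4K20 list was at a log2 of 2.32 in microglia-like and 2.59 in border macrophage-like cells, and the demethylase gene Kdm6b of the autism list at 2.44 in the latter.

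Neuron-like cells had all 24 synaptic genes higher, led by the vesicle calcium sensor Syt1 (log2 5.03 in excitatory and 5.18 in inhibitory neuron-like cells). The NMDA receptor gene Grin2b, on both the autism and the synaptic list, was at 4.54 in excitatory and 3.33 in inhibitory neuron-like cells, and Cplx1, which encodes a regulator of vesicle release, at 4.46 in the inhibitory class. Grin2a, the NMDA receptor gene of the schizophrenia exome list, reached 149 ± 32.7 CPM in excitatory neuron-like (log2 4.14, SE 0.17) and 112 ± 18.8 CPM in inhibitory neuron-like cells (log2 3.66). The autism gene Tbr1, which is also a marker used for naming, was at 4.60 in excitatory neuron-like cells, and Kdm6b at -2.18. Of the H2A.Z list 10 genes were lower in excitatory neuron-like cells, with H2afv at -2.29 and Nap1l1 at 0.74, and 13 in inhibitory neuron-like cells, with the remodeller subunit gene Actl6a at -2.09 and Yeats4 at 0.85. The reader of methylated H4K20 L3mbtl1 was the most raised of its list in both (log2 2.48 and 2.63), at 3.63 ± 0.590 and 4.25 ± 2.28 CPM. The activity gene Npas4 was at 3.63 in excitatory and 3.66 in inhibitory neuron-like cells. Genes of oxidative phosphorylation were higher, 20 of 24 in excitatory and 22 in inhibitory neuron-like cells, with Cox5a at 0.94 and 1.45 and Ndufa4 at 1.32 in the latter. Of 22 interferon response genes 20 were lower in each, with Rtp4 at -3.61 in the excitatory and Bst2 at -2.75 in the inhibitory class. The camera calls for synaptic genes (adjusted p = 0.530 and 0.469 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.640 and 0.469 with an estimated correlation) and interferon response (adjusted p = 0.530 and 0.469 with an estimated correlation) were made with the preset correlation alone.

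Astrocyte-like and ependymal-like cells carried high levels of immediate early transcripts. In astrocyte-like cells 19 of 21 such genes were higher, led by the transcription factors Fos, at 10411 ± 3222 CPM (log2 3.80, SE 0.16, 10 of 10 libraries), and Egr1 (log2 3.53). In ependymal-like cells 19 were higher as well, led by Fos (log2 2.97) and the phosphatase gene Dusp1 (log2 2.96). All 20 genes of cholesterol synthesis were higher in astrocyte-like cells, with Idi1 at 2.62 and Msmo1 at 2.47, and 17 of 22 interferon response genes, with Ifit3 at 3.22. The lipid carrier gene Apoe was at 2.87 in astrocyte-like cells. Of the H2A.Z list H2afv was at 1.09 and H2afz at -1.25 there, of the H4K20 list the demethylase gene Phf8 at 0.68, and of the schizophrenia exome list Sp4 at 1.15. Ependymal-like cells had the microtubule severing gene Katnal2 at 4.01 and Asxl3 at -2.52 from the autism list, the chromatin remodelling helicase gene Ruvbl2 at 2.55, the chaperone gene Hsp90aa1 at 2.33, the p53 targets Eda2r at 3.43 and Cdkn1a at 2.26, and the chemokine gene Cxcl10 at 3.85. The camera calls for immediate early genes in these classes (adjusted p = 0.169 and 0.775 with an estimated correlation) and for cholesterol synthesis and interferon response in astrocyte-like cells (adjusted p = 0.311 and 0.658 with an estimated correlation) were made with the preset correlation alone. Every library came from sorted cells, so levels before the cells were handled were not measured. The same limit holds for the immediate early, heat shock and chemokine genes of the other classes.

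Endothelial-like cells had the small heat shock protein gene Hspb1 at a log2 of 6.20, the adhesion gene Icam1 at 4.34, the inhibitor gene Nfkbia at 3.70 and the transcription factor Klf2 at 3.68. The interferon gene Ifi44 was at 3.88 and the scaffold gene Shank3 of the autism list at 2.58 in endothelial-like cells. Fibroblast-like cells had 21 of 22 interferon response genes higher, with Ifit3 at 3.89, a call made with the preset correlation alone (adjusted p = 0.615 with an estimated correlation). The calcium channel gene Cacna1g of the schizophrenia exome list was at 2.12 and Foxp1 of the autism list at 1.54 in fibroblast-like cells.

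In each class edgeR called between 3464 and 6232 of 15512 genes higher and between 4093 and 7105 lower. Camera called 68 of 180 tests of 15 lists in 12 classes with the preset correlation, and the 7 that held with an estimated correlation are the ones given above with an adjusted p under the threshold: microglial activation in both macrophage classes, myelin in committed and mature cells, cholesterol synthesis in mature cells, and H2A.Z exchange and the cell cycle in neuroblast or progenitor-like cells. Without the replicate block, 4 tests held with an estimated correlation. Autism genes were called in 2 classes, both lower, and immediate early genes in 9 (5 higher, 4 lower). Schizophrenia exome genes were called in 0 of 12 classes (1 at an unadjusted p under 0.05, 0 with an estimated correlation) and p53 targets in 0 (0 at an unadjusted p under 0.05, 0 with an estimated correlation). Summed over the 12 classes, with a gene counted once in each class that called it, autism genes gave 92 higher and 118 lower calls (92 and 119 adjusted over the list alone). H2A.Z exchange gave 81 and 94 (81 and 95 adjusted over the list alone). The H4K20 list gave 56 higher and 67 lower calls (57 and 67 adjusted over the list alone), and schizophrenia exome genes 34 and 46 (34 and 47 adjusted over the list alone). These sums are to be read beside the large counts called among all genes in each class, given above, and show no enrichment by themselves.

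Libraries with names ending in F and in M were then compared within each class, with that letter taken as the group. A rerun suffix in the file names also splits the libraries and is taken up below. The genes that differed were on the sex chromosomes. Xist, the RNA that silences an X chromosome, was at 813 ± 316 CPM in astrocyte-like cells of the 4 F libraries and 0.304 ± 0.253 CPM in those of the 6 M libraries, and its antisense gene Tsix at 126 ± 54.1 and 1.59 ± 0.903 CPM. The Y-linked helicase gene Ddx3y had 0 counts in astrocyte-like cells of the F libraries and 118 ± 20.1 CPM in the M libraries, at least 1675-fold higher, with the floor of 3 counts taken over the F group. Eif2s3y, a Y-linked translation factor gene, had 0 counts in F and 42.5 ± 8.54 CPM in M libraries, at least 604-fold higher. The Y-linked demethylase genes Kdm5d and Uty were at 17.0 ± 1.12 and 17.7 ± 4.73 CPM in the M libraries, with 2 and 0 counts in the F libraries.

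Each of the 12 classes gave 4 to 6 called genes, and over the classes these were 6 different genes: Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. Xist did not pass in fibroblast-like cells (adjusted p = 0.138; F 696 ± 189 and M 6.32 ± 14.7 CPM) or inhibitory neuron-like cells (adjusted p = 0.102; F 460 ± 204 and M 7.68 ± 12.5 CPM). No autosomal gene was called by edgeR in 129854 tests, of which 4789 (3.69%) had an unadjusted p under 0.05; DESeq2 called 14. Neither Anp32e nor Kmt5a was called in any class, with log2 differences of -0.15 and 0.01 in neuroblast or progenitor-like cells and -0.08 and -0.06 in astrocyte-like cells.

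The list of X-inactivation and escape was higher in F libraries in all 12 classes under both correlations, with an adjusted p between 0.000244 and 0.0276 with an estimated correlation. The list holds Xist itself and was not tested without it, so these calls follow at least in part from Xist. Adjusted over the list alone, 44 calls were made over the classes, against 10 adjusted over all genes, which were the calls of Xist. In astrocyte-like cells the escape genes Kdm6a (log2 0.83, SE 0.17), Ddx3x (0.58, SE 0.15), Kdm5c (0.56, SE 0.10) and Eif2s3x (0.49, SE 0.10) had adjusted p between 0.187 and 0.786 over all genes, and 5 genes of the list, Xist included, passed when adjusted over the list alone. Calls for other lists were made with the preset correlation alone. Autism genes were called higher in F in 9 classes (lowest adjusted p = 0.165 with an estimated correlation), schizophrenia exome genes in 4 (lowest adjusted p = 0.102 with an estimated correlation) and synaptic genes in 5, with 1 lower (lowest adjusted p = 0.650 with an estimated correlation). Immediate early genes were higher in 6 and lower in 1 (lowest adjusted p = 0.291 with an estimated correlation; 0 genes over all genes and 9 adjusted over the list alone). Oxidative phosphorylation was lower in 6 classes (lowest adjusted p = 0.488 with an estimated correlation), and the cell cycle lower in 4 and higher in 1 of 10 classes (lowest adjusted p = 0.291 with an estimated correlation). Heat shock and cholesterol synthesis were each called higher in 1 class and lower in 1 (lowest adjusted p = 0.454 and 0.650 with an estimated correlation). H2A.Z exchange, microglial activation, interferon response, p53 targets and myelin were called lower in 1 class each (lowest adjusted p = 0.291, 0.486, 0.660, 0.459 and 0.683 with an estimated correlation), and H4K20 methylation in 0 classes (0 at an unadjusted p under 0.05, 0 with an estimated correlation).

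The labels do not say that the libraries came from separate animals, so these p-values measure the spread between libraries. Among the 6 libraries with a rerun suffix, 3 F and 3 M, of which 2 F entered for endothelial-like and mature oligodendrocyte-like cells, between 1 and 7 genes were called per class, 4 of them autosomal over all classes, and with the suffix as a covariate 1 autosomal gene was called; by date in the library names, only 1 date held both letters, with 1 library each, and no comparison within dates was run. Without F replicate 2, F replicate 5 or M replicate 10 the autosomal count was 1, 2 and 1.

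Guide UMIs, which stand for the viral vector, were compared across the classes to see which sorted cells carried it. They were highest relative to the mean of the other classes in ependymal-like (log2 0.79, SE 0.15), excitatory neuron-like (0.69, SE 0.15) and inhibitory neuron-like cells (0.66, SE 0.15), with adjusted p over classes of 5.86e-06, 4.53e-05 and 8.58e-05 in edgeR. They were lower in endothelial-like (-0.57), mature oligodendrocyte-like (-0.54), OPC-like (-0.50), committed oligodendrocyte-like (-0.44) and neuroblast or progenitor-like cells (-0.43). The call in mature oligodendrocyte-like cells ended with at least 1000 genes per cell (-0.25), 50 cells per sum (-0.21) or shared barcodes removed (-0.41). That in committed oligodendrocyte-like cells ended with at most 5% mitochondrial UMIs (-0.42) or 50 cells per sum (-0.38), and that in neuroblast or progenitor-like cells with thinned counts (-0.35). Astrocyte-like (0.14), microglia-like (0.15), border macrophage-like (0.13) and fibroblast-like cells (-0.09) did not pass. At least 1 guide was called in 42.7% ± 20.1 of excitatory neuron-like, 37.6% ± 23.7 of inhibitory neuron-like and 31.8% ± 20.6 of ependymal-like cells, whose medians were 4323, 5280 and 8474.5 UMIs. It was called in 7.98% ± 7.26 of microglia-like and 3.92% ± 4.25 of endothelial-like cells, with medians of 1968.5 and 2107.5 UMIs. The purity of the sort was not tested, and no class is known to lack the vector, so no share stands for background. Without the replicate block no class passed (adjusted p = 0.878 for each), with ependymal-like cells at 0.43, excitatory neuron-like at 0.61, inhibitory neuron-like at 0.62, endothelial-like at -0.37, mature oligodendrocyte-like at -0.39, OPC-like at -0.51, committed oligodendrocyte-like at -0.18 and neuroblast or progenitor-like at -0.40, and the call in committed oligodendrocyte-like cells ended without F replicate 1 (-0.34), M replicate 6 (-0.43) or F replicate 9 (-0.41).

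The comparison the study was built for sets cells with guides against Anp32e or Kmt5a beside cells with control guides. Of 93336 cells, 73256 had no called target, 14756 had 1 and 5324 had several. The only guide that could serve as a control was 1 against GFP, and with at least 20 cells of each arm no class had a library to test, so arms of at least 5 cells, and cells with other targets as controls, were chosen after the cell numbers had been seen. Guide 1 of Anp32e was called in 206 cells and guide 2 in 4, so the results for Anp32e rest on 1 guide; the 2 guides of Kmt5a were called in 165 and 113 cells. Against 5 cells with other targets per guide cell, matched on library and class in 9 libraries, each gene's own transcript was lower. Anp32e was at 112 CPM with its guides and 141 CPM in controls (206 and 1030 cells, log2 -0.32, SE 0.12, adjusted p = 0.0417 over the targets tested, lower in 7 of 9 libraries). Kmt5a was at 42.4 CPM with its guides and 53.6 CPM in controls (275 and 1375 cells, log2 -0.39, SE 0.15, adjusted p = 0.0417 over the targets tested, lower in 6 of 9 libraries). With controls matched within clusters the log2 changes were -0.44 (lower in 9 of 9 libraries) and -0.36 (lower in 7 of 9). With each guide alone they were -0.39 (SE 0.12) for guide 1 of Anp32e, -0.52 (SE 0.22) for guide 1 of Kmt5a and -0.15 (SE 0.22, unadjusted p = 0.507) for guide 2 of Kmt5a. Against the GFP guide the own transcripts did not pass: over all cells Anp32e was at -0.22 (SE 0.22, unadjusted p = 0.337, lower in 3 of 5 libraries) and Kmt5a at -0.21 (SE 0.24, unadjusted p = 0.404, lower in 4 of 5). In ependymal-like cells they were at -0.21 (SE 0.40) and 0.12 (SE 0.34), and in astrocyte-like cells Anp32e was at -0.40 (SE 0.30). With the guides of the other gene and matched controls, Anp32e was at -0.22 (SE 0.13, unadjusted p = 0.0981 in edgeR) with Kmt5a guides. Kmt5a was at 0.19 (SE 0.14, unadjusted p = 0.189 in edgeR) with Anp32e guides. The changes of Anp32e with the guides of either gene were not compared in a test. Over all genes tested with matched controls the adjusted p of the own transcript was 0.787 for Anp32e and 0.795 for Kmt5a. The own-transcript call of Anp32e ended without M replicate 7 (-0.26) or F replicate 9 (-0.26), and that of Kmt5a without F replicate 5 (-0.26). The same matched test on 32 other targets called the own transcript lower for 9 and higher for 4. A call in this test is thus weak evidence by itself of an effect of the guides.

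**Figure D2:**
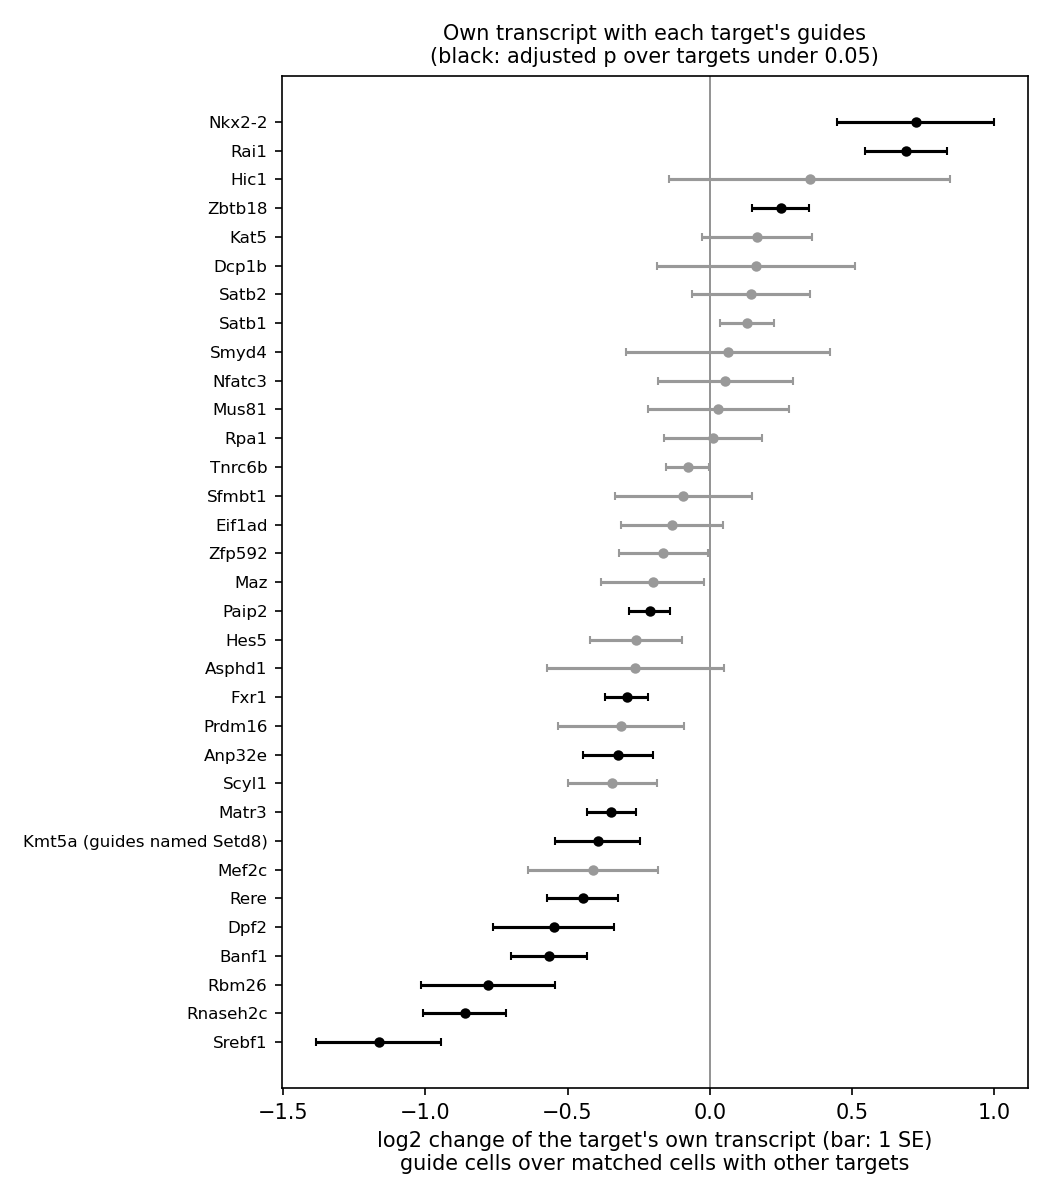
Log2 change of each target's own transcript in cells with its guides against matched cells with other targets, with bars of 1 SE; black points passed over the targets tested and grey points did not, and not every target tested is drawn. Anp32e is at -0.32 and Kmt5a at -0.39, and the points run from Srebf1 at -1.16 to Nkx2-2 at 0.72.

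Beyond the targets, calls against the GFP guide were made in astrocyte-like cells, and they included markers of that class. With Anp32e guides against the GFP guide (30 and 51 cells, 4 libraries) edgeR called 4 of 2364 genes: the water channel gene Aqp4 (log2 -1.23, SE 0.22), the calcium-binding gene S100b (-2.64, SE 0.53) and the differentiation inhibitor Id2 (-1.08, SE 0.21) fell, and Mia rose (1.66, SE 0.33). With Kmt5a guides (51 and 43 cells, 3 libraries) 21 of 2981 genes were called, and Aqp4 (-1.22), S100b (-3.40), the fatty acid carrier gene Fabp5 (-1.08), the bicarbonate transporter gene Slc4a4 (-1.19) and Ntsr2 (-1.21) fell and kept their calls without each of the 3 libraries. Cd14 (-2.63) and Ccl4 (1.75) kept theirs in the 2 such tests that gave a value. Other calls ended: Cxcl10 (-1.81) was at -0.67 without replicate 10, Emd (-1.10) at -0.70 without replicate 5 and -1.33 without replicate 6, Creb5 (1.58) at 1.40 without replicate 5, Eftud2 (1.16) at 0.30 without replicate 6, and Mia (1.26) at 0.90 without replicate 5 and 1.20 without replicate 6. All 4 genes called with Anp32e guides were called with Kmt5a guides in the same direction, but both tests used the same control cells; Aqp4 and Ntsr2 are astrocyte markers, and Mia an ependymal marker, of the lists that named the classes. With other targets as control, 3 of the 4 were called for Anp32e (Aqp4 -1.10, S100b -1.98, Id2 -1.01), and 2 of the 4 for Kmt5a (Aqp4 -0.87, S100b -2.76), for which 10 of the 21 were called. DESeq2 called 0 and 3 genes, guide calls at a binomial p under 1e-6 gave 0 and 0, and the Anp32e count was 0 without replicate 6, 0 without replicate 8 and 2 without replicate 10. Without replicates 6 and 8 Aqp4 was at -1.02 and -1.08 with Anp32e guides; Id2 (-1.08) and Mia (1.39) were not called without replicate 5, nor Id2 (-1.15) without replicate 10. With Kmt5a guides in inhibitory neuron-like cells, which had no test against the GFP guide, 23 of 11404 genes were called against other targets (16 and 777 cells, 3 libraries), among them Gm17251 (4.60) and, of the microglial activation list, Il1b (4.00), Ccl4 (3.36), Ccl2 (3.22) and Ccl3 (2.53), which rose. The inhibitory neuron markers Sst (-2.66), Npy (-1.85) and Vip (-1.69) fell in that test; no library was left out there.

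In ependymal-like cells edgeR called 0 of 4954 genes with Anp32e guides (33 and 41 cells, 3 libraries; 96 at an unadjusted p under 0.05, DESeq2 0) and 0 of 4719 with Kmt5a guides (64 and 55 cells, 5 libraries; 195 at an unadjusted p under 0.05, DESeq2 0). Against other targets in ependymal-like cells, 4 of 13574 genes were called for Anp32e (33 and 2109 cells, 3 libraries), among them the mural markers Rgs5 (4.35) and Vtn (2.22), which rose. For Kmt5a 25 of 11925 were called (69 and 2934 cells, 6 libraries), among them the cell cycle genes Cenpf (-1.44), Top2a (-1.34) and Cdk1 (-1.31), of which the first 2 are markers of neuroblasts or progenitors, and Gpnmb (3.25) and Spp1 (2.46) of the microglial activation list. No library was left out in these tests against other targets. Over all cells against the GFP guide the counts were 0 of 9750 for Anp32e (298 at an unadjusted p under 0.05, DESeq2 0) and 0 of 10072 for Kmt5a (284 at an unadjusted p under 0.05, DESeq2 2). Against matched other targets, the inhibitory neuron peptide gene Sst (log2 -3.15) and Npnt (-1.30) were called for Anp32e among 11109 genes (636 at an unadjusted p under 0.05, DESeq2 2), and 0 of 12206 for Kmt5a (682 at an unadjusted p under 0.05, DESeq2 1). With controls matched within clusters edgeR called 0 of 11073 genes for Anp32e (543 at an unadjusted p under 0.05; DESeq2 was not run there), and Sst is an inhibitory neuron marker of the lists that named the classes. The GFP guide tested the same way gave 5 called genes, and the 43 targets had a median of 2 and a highest count of 16; the counts of 2 and 0 did not exceed that median. The call of Sst ended without F replicate 5 (-2.23) or M replicate 7 (-2.23), and that of Npnt without M replicate 6 (-1.11) or 7 (-1.10). The Anp32e count was 6 without F replicate 1, 1 without M replicate 6, 0 without M replicate 7 and 8 without M replicate 8; the Kmt5a count was 3 without F replicate 2, 1 without F replicate 5, 3 without M replicate 7, 6 without M replicate 8 and 1 without M replicate 10. Of 93 camera tests 19 were called with the preset and 0 with an estimated correlation (lowest adjusted p = 0.276 with an estimated correlation). The share of guide cells by class passed in none of 13 exact permutation tests over both targets (smallest unadjusted p = 0.0195, adjusted p = 0.254, exact, for inhibitory neuron-like cells at 7.44% with Anp32e guides and 10.0% among cells with other targets).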

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

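The tests on guide shares by class and on Xist in M libraries were chosen after those results had been seen, as were the comparisons of guide cells with GFP guide or matched cells; the splits of F and M libraries were planned.

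In 9 of 88 groups of libraries (10.2%, over 47 measures) 1 library stood far from the others of its group, where chance marks about 1 in 20 groups. M replicate 7 had 40385 barcodes, against at most 11159 in the other M libraries, and a mature oligodendrocyte-like share of 2.70%, against at most 1.15%. M replicate 4 had low Anp32e in inhibitory neuron-like cells (56.2 CPM, the next at 76.4) and low Kmt5a in OPC-like (41.0 CPM, the next at 70.9) and committed oligodendrocyte-like cells (76.1 CPM, the next at 129). M replicate 8 had high Anp32e in microglia-like cells (198 CPM, the next at 132). F replicate 5 had high Anp32e in fibroblast-like cells (120 CPM, the next at 78.0). F replicate 1 had low Kmt5a in excitatory neuron-like cells (28.4 CPM, the next at 44.2), and F replicate 2 high Kmt5a in microglia-like cells (122 CPM, the next at 85.1).

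Guides against 40 further targets lie outside the comparisons above, and 13996 cells carried 1 of those targets. Against matched cells with other targets, 32 of these genes could be tested for their own transcript, and 19 were lower and 13 higher. Of these, 9 lower changes passed over the targets tested, in Srebf1 (log2 -1.16, lower in 9 of 10 libraries), Rnaseh2c (-0.86, 8 of 8), Rbm26 (-0.78, 6 of 7), Banf1 (-0.57, 8 of 9), Dpf2 (-0.55, 9 of 10), Rere (-0.45, 8 of 9), Matr3 (-0.35, 8 of 9), Fxr1 (-0.29, 8 of 9) and Paip2 (-0.21, 8 of 10). There were 4 higher changes that passed, and they included the transcripts of Nkx2-2 (0.72), Rai1 (0.69) and Zbtb18 (0.25), lower in only 2, 1 and 2 of 10 libraries.

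Guides were called in a mean of 33.5% of ependymal-like, neuron-like and astrocyte-like cells and 7.32% of endothelial-like, microglia-like and mature oligodendrocyte-like cells, a ratio of 4.57. The classes were grouped after the shares had been seen, and committed oligodendrocyte-like cells, in neither group, had a share of 26.8% ± 13.4, above the 21.8% ± 16.3 of astrocyte-like cells. A difference in depth could carry part of this, since among cells of 1500 to 6000 UMIs the ratio was 2.53, with a lowest value of 1.15 over libraries and over 3 in 2 of 9, counting 1 library where the lower classes were at 0. Free guide RNA could as well: with a clear top guide the ratio was 4.49, but the lowest over libraries was 0.755, and it was over 3 in 7 of 10, counting 2 libraries where the lower classes were at 0. Free guide RNA was expected to leave under 30% of cells with a called guide with a top guide 3 times the next, and the shares were 43.9% ± 8.35 and 66.4% ± 16.5 in 6 libraries, above that bound. These cells had already passed a guide call against the background, which favours cells with 1 dominant guide. The shares therefore decide nothing about free guide RNA. The ratios by library fell on both sides of the bounds set for either explanation, so both stay open, and no biological explanation was tested.

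Xist UMIs were found in M replicates 3 and 4, at 3.96 and 3.34 CPM. They are consistent with molecules carried over from F replicate 2, since 80.6% and 98.7% lay in barcodes that F replicate 2 also holds, and the rest left 0.780 and 0.0452 CPM, against 0.119 to 0.516 CPM in M replicates 6, 8 and 10, 1.74 CPM in M replicate 7 and 291 to 842 CPM in F libraries. The rest in replicate 3 thus exceeded 3 of the 4 other M libraries. Outside the shared barcodes 1 barcode in replicate 3 and 0 in replicate 4 had at least 3 Xist UMIs and none of the Y-linked genes. For replicate 3 this argues against cells of an F animal outside the shared barcodes. For replicate 4 it decides nothing, since 74 of its 75 Xist UMIs lay in shared barcodes. Inside the shared barcodes 5 and 2 barcodes were of this kind, and cells of an F animal were not tested there. M replicate 7 had 28 barcodes of this kind among 40385, all outside those that F replicate 2 holds, and what they hold was not tested. Replicates 2, 3 and 4 shared between 13.3% and 14.6% of barcodes, while the 42 other pairs shared at most 1.23%. Elsewhere Xist followed the letter of the names, and the Y-linked genes gave a measure of sex apart from the names. Together they were at 0.0677 to 0.385 CPM in the F libraries and 136 to 177 CPM in the M libraries, opposite to Xist. Both measures thus go with the sex that the names appear to give, which the labels do not state.

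Splits of the same libraries into groups of the same sizes tested whether chance could give as many F against M genes. For the number of genes, the share of splits with as many was under 0.05 in 8 of 12 classes. These shares were not adjusted over the classes, which come from the same libraries, so they do not exclude chance. As many genes were called in 3 of 100 splits for OPC-like (6 called, highest other split 73), 4 of 100 for astrocyte-like (6, highest other 1298), 4 of 100 for border macrophage-like (5, highest other 130), 4 of 84 for endothelial-like (4, highest other 1735), 3 of 100 for excitatory neuron-like (6, highest other 923), 4 of 100 for fibroblast-like (5, highest other 479), 3 of 100 for inhibitory neuron-like (5, highest other 245) and 3 of 100 for neuroblast or progenitor-like cells (6, highest other 98). Chance cannot be excluded either, at shares of 0.05 or more, for committed oligodendrocyte-like (5 of 56 splits, 6 called, highest other 325), ependymal-like (7 of 100, 6 called, highest other 906), mature oligodendrocyte-like (3 of 56, 4 called, highest other 227) and microglia-like cells (5 of 100, 6 called, highest other 605). The number does not weigh which genes were called: in ependymal-like cells Eif2s3y and Ddx3y had 0 counts in F and 3776 and 6980 in M libraries, with 0 autosomal calls, while other splits reached 881 autosomal calls. Chance is therefore no account of these Y-linked genes. In each class another split called several times the real count, which points to a structure of the samples, and in 11 of 12 classes the split with the most calls put replicates 5 and 7 on the same side. The classes share their libraries, many splits put any given pair on the same side, and no other pair was counted. That count therefore does not single out replicates 5 and 7. The split by rerun suffix, in 10 classes, called between 0 and 3 genes and was as large as the real one in 0.

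For guides, arms were exchanged within libraries. Chance cannot be excluded for Anp32e against matched cells (42 of 60 splits, 2 called, highest other 7). Where 0 genes were called every split is as large, so the exchange decides nothing, as for Kmt5a against matched cells (60 of 60 splits, 0 called, highest other 5). The splits were too few for a share under 0.05 for Anp32e against the GFP guide over all cells (16 of 16 splits, 0 called, highest other 93), in astrocyte-like cells (1 of 8, 4 called, highest other 1) and in ependymal-like cells (4 of 4, 0 called, highest other 0), and for Kmt5a over all cells (16 of 16, 0 called, highest other 1), in astrocyte-like cells (1 of 4, 21 called, highest other 0) and in ependymal-like cells (16 of 16, 0 called, highest other 1).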

How the results depend on the processing

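The removal of barcodes shared between libraries, all settings for guide UMIs by class, the list tests by class with an estimated correlation and no replicate block, and the guide controls, stricter guide calls and matching within clusters were chosen after the data had been seen; the other alternatives were planned. Where a value changed below, the cause was not tested.

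For the targets by class, calls outside astrocyte-like (Anp32e) and ependymal-like cells (Kmt5a) kept direction and side of the threshold in every setting that gave a value; the values near 0 that did not pass changed sign. Anp32e in astrocyte-like cells was no longer called with at least 1000 genes (0.061), at most 5% mitochondrial UMIs (0.080), 50 cells per sum (0.15), no replicate block (0.061) or shared barcodes removed (0.063), and ranged from 0.048 to 0.23 as each library was left out. Anp32e in border macrophage-like cells was -0.034 without a filter on low counts and -0.091 with thinned counts (-0.051 to 0.17 with a library left out), and in microglia-like cells -0.024 with RLE factors, -0.051 with DESeq2 and -0.024 with thinned counts (-0.0096 to 0.18). Kmt5a in OPC-like cells was -0.024 with 50 cells per sum and -0.072 with thinned counts (-0.022 to 0.081). Kmt5a in border macrophage-like cells was 0.049 with 1000 genes, 0.039 with 5% mitochondrial UMIs, 0.15 with 50 cells, 0.038 with no replicate block and 0.053 with shared barcodes removed (-0.11 to 0.094). Kmt5a in ependymal-like cells was called lower with 1000 genes (-0.26), 5% mitochondrial UMIs (-0.24), doublets kept (-0.17), 50 cells (-0.24), no replicate block (-0.24) and shared barcodes removed (-0.26), and ranged from -0.27 to -0.16.

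Guide UMIs without the replicate block passed in no class: OPC-like -0.51, committed oligodendrocyte-like -0.18, endothelial-like -0.37, ependymal-like 0.43, excitatory neuron-like 0.61, inhibitory neuron-like 0.62, mature oligodendrocyte-like -0.39 and neuroblast or progenitor-like -0.40. In astrocyte-like cells they were -0.057 with 1000 genes, -0.0011 with 5% mitochondrial UMIs, -0.13 with no replicate block and -0.044 with shared barcodes removed (-0.016 to 0.14 with a library left out). Committed oligodendrocyte-like cells lost the call with 5% mitochondrial UMIs (-0.42) and 50 cells (-0.38), with a range from -0.55 to -0.34; mature oligodendrocyte-like cells with 1000 genes (-0.25), 50 cells (-0.21) and shared barcodes removed (-0.41); neuroblast or progenitor-like cells with thinned counts (-0.35). Fibroblast-like cells were at 0.0079 with RLE factors and 0.0031 with thinned counts (-0.10 to 0.012).

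Of the calls on lists by class, 7 held with an estimated correlation and 4 with an estimated correlation and no replicate block; for F against M, 12 held. F against M in OPC-like cells gave 10 genes without a filter on low counts; DESeq2 gave 13 in astrocyte-like, 15 in ependymal-like and 10 in excitatory neuron-like cells; endothelial-like cells gave 0 with 50 cells per sum; and with the rerun libraries alone, endothelial-like cells gave 2, fibroblast-like 1, mature oligodendrocyte-like 2 and microglia-like 3. The autosomal count was 4 without a filter on low counts, 14 with DESeq2, 1 with 5% mitochondrial UMIs, 1 with the rerun suffix as a covariate and 4 with the rerun libraries alone, and ranged from 0 to 2 with a library left out (2 without F replicate 5, 1 without F replicate 2 or M replicate 10). The mature oligodendrocyte-like share was 1.87% at Leiden resolution 0.5. Of the genes named for F against M, 708 values kept their side with a library left out, 27 lost and 2 gained a call, and under other settings 686, 24 and 12. Of the genes named with guides, 52 values kept the call with a library left out and 40 lost it, and under other settings 161 and 92. Class shares kept within their spread in all 140 values with a library left out.

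Anp32e guides against the GFP guide in astrocyte-like cells gave 9 genes without a filter on low counts, 0 with DESeq2, 0 with calls at 1e-6, 0 with calls of at least 5 UMIs and 17 with other targets as control (0 to 4 with a library left out: 0 without replicate 6 or 8, 2 without 10). In ependymal-like cells they gave 2 without a filter, 7 with 1000 genes and 4 with other targets as control, and over all cells 36 without a filter. Against matched cells they gave 88 without a filter, 0 with calls of at least 5 UMIs and 0 with controls matched within clusters (0 to 8 with a library left out: 6 without replicate 1, 1 without 6, 0 without 7, 8 without 8). Kmt5a guides in astrocyte-like cells gave 3 genes with DESeq2, 9 with 5% mitochondrial UMIs and 0 with calls at 1e-6. In ependymal-like cells they gave 12 without a filter, 5 with calls at 1e-6, 2 with calls of at least 5 UMIs and 25 with other targets as control; over all cells 58 without a filter and 2 with DESeq2. Against matched cells they gave 98 without a filter, 1 with DESeq2, 3 with calls at 1e-6 and 2 with calls of at least 5 UMIs (0 to 6 with a library left out: 3 without replicate 2, 1 without 5, 3 without 7, 6 without 8, 1 without 10). The own transcript of Anp32e ranged from -0.37 to -0.26 with a library left out, without a call when replicate 7 (-0.26) or 9 (-0.26) was, and that of Kmt5a from -0.52 to -0.26, without a call when replicate 5 was left out (-0.26).

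Settings that gave no value were the planned guide test with at least 20 or 50 cells per arm, Leiden resolution 0.5 for the shares of border macrophage-like, committed oligodendrocyte-like and mural-like cells, which had no cluster there, and F against M in mature oligodendrocyte-like cells with 1000 genes or 50 cells per sum and in committed oligodendrocyte-like cells with 50 cells per sum. In simulated data 4% of 2-fold F against M changes were recovered in endothelial-like, 11% in fibroblast-like, 14% in mature oligodendrocyte-like, 21% in committed oligodendrocyte-like and 28% in microglia-like cells. Endothelial-like, fibroblast-like, mature oligodendrocyte-like and microglia-like cells had medians of 2107.5, 4303.5, 2774 and 1968.5 UMIs, so recovery did not follow depth alone, and most 2-fold changes in these 5 classes were missed.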

Other observations

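The comparisons between pairs of classes in this part were chosen after the results by class had been seen.

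Along the oligodendrocyte lineage, myelin genes rose at an early and a late step, and cholesterol synthesis rose at the late one. The steps were not compared with each other in a test. From OPC-like to committed oligodendrocyte-like cells, edgeR called 5137 of 15512 genes. The replication genes Mcm5 (log2 -3.90) and Mcm3 (-3.39) fell with 17 of 22 cell cycle genes, and cholesterol synthesis moved down in 8 of 20 genes, with Dhcr7 at -0.89 and Idi1 at -0.80; both camera calls were made with the preset correlation alone (adjusted p = 0.414 and 0.862 with an estimated correlation). Myelin genes were already higher, 11 of 14, with Mag at 5.80 (adjusted p = 0.0222 with an estimated correlation). From committed to mature cells, in 7 libraries, all 20 genes of cholesterol synthesis rose, with Hmgcs1 at 3.36 (adjusted p = 0.00834 with an estimated correlation, higher in 7 of 7 libraries), and all 14 myelin genes, with Mal at 10.07 and Ermn at 9.67; 11 of these are markers that named the mature class, so their rise follows in part from the naming. At that step 15 of 21 genes of H2A.Z exchange changed, 13 of them lower, with Nap1l1 at -1.49 and Anp32b at -1.32 (adjusted p = 0.126 with an estimated correlation).

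Microglia-like cells differed from border macrophage-like cells in stress and interferon genes. The heat shock genes Hspa1b (log2 -2.81) and Hspa1a (-2.71), the interferon genes Ifitm3 (-2.39) and Ifi27l2a (-2.34), and the immediate early genes Junb (-2.02) and Klf4 (-1.83) were lower in microglia-like cells, in 10 of 10 libraries each. Camera called these lists with the preset correlation alone (adjusted p = 0.122, 0.122 and 0.270 with an estimated correlation). In the same way it called the cell cycle lower and oxidative phosphorylation higher in microglia-like cells (adjusted p = 0.578 and 0.580 with an estimated correlation). Kmt5a was higher in microglia-like cells (log2 0.37, adjusted p = 0.0220, 7 of 10 libraries).

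One unnamed cluster of 2677 cells, 96.0% of them from M replicate 7, had Nppa and Cck among its top genes, and another of 954 cells, 83.8% from F replicate 1, had Ndnf, Lhx1 and Reln. An unnamed cluster of 970 cells over 10 libraries had Igfbpl1, Dcx and Prokr2 among its top genes. Its markers were mostly those of inhibitory neurons, but another class had the higher mean marker fold. A cluster of 1584 cells over 8 libraries had Il1b, Cd14 and Rgs1 among its top genes and was left unnamed because its top 10 genes held more markers of another class than microglia.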
